A study of Nicotiana tabacum with 12 samples.

How the data were processed

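Messenger RNA abundance was measured in roots of tobacco (Nicotiana tabacum) by RNA sequencing of 12 libraries, 3 in each of 4 groups that the sample titles code as WTR, TWTR, CR and TCR. The titles do not spell these codes out, and every sample carries the same protocol text, on an NtLHT1 mutant kept in hydroponic low nitrogen solution for 15 days. The codes are therefore used as given, and no genotype or nitrogen supply was assigned to any of them. Nothing in the labels says that replicates came from separate plants, so all p-values measure only the spread between these libraries, which may be technical. No batch or date is given in the labels.

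Per the labels' protocols, the authors extracted RNA with TRIzol, enriched messenger RNA, sequenced on a DNBSEQ-T7 instrument with a stated read length of 300 bp, and cleaned the reads with fastp. Clean reads were aligned with STAR, also named in the submitters' processing notes, transcripts were assembled with StringTie2, and the assembly was set against known genes with Cuffcompare, per the labels' protocols. The genome build, the annotation release, the program that made the abundance values and all versions were not stated in the sources used here. The only trace of the annotation is the prefix Nitab4.5 that all identifiers carry. The values are the authors' deposited FPKM (fragments scaled to transcript length in kilobases and to the mapped fragments of the library), per the file headers, in 1 table of 25273 gene models with 1 transcript identifier each. FPKM divides by transcript length and by the library total, so a few very abundant transcripts can shift all other values of a library, and reads shared by near-identical gene copies, which are common in an allotetraploid such as tobacco, may be split between them in a way the table does not record.

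All identifiers have the form Nitab4.5 with a scaffold part and a gene part, and the table does not pair them with gene names. None of them (0 of 25273) was found in the RefSeq gene table of assembly ASM71507v2, so no identifier could be given a name. The gene lists fixed before the data were examined, which select genes by product name, could not be used, and NtLHT1 itself was not analysed here. The labels could therefore not be checked by the level of the mutated gene. With no names, the naming rule fixed before the data were examined took, in each of 5 contrasts, the 2 models with the largest positive and the 2 with the largest negative log2 difference. They had to pass the threshold with a mean of at least 5 FPKM in the higher group and, in the contrasts of 2 groups, with no overlap between the replicates of the groups. A model named by 2 contrasts counts under both, and 17 different models were named.

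Depth was read only in relative terms. FPKM carries no fragment totals, so absolute depth is unknown and no counting intervals were computed. Among 3433 models at 0 in at least 4 libraries, values of at least 0.2 FPKM in a pair of libraries often stand for the same small number of fragments, and their commonest ratio gives the inverse ratio of depths. With CR replicate 1 set to 1, CR replicate 2 came to 1.81 and the other 10 libraries lay between 0.914 and 1.14. A second route, by way of WTR replicate 1, differed by at most 0.78%. Deposited FPKM summed to between 1099061 and 1154691 per library.

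Values were transformed to log2(FPKM + 1), and 19929 models with a mean of at least 1 FPKM over the 12 libraries were tested with limma 3.58.1 in R 4.3.3, while 5344 models below that mean were not. A linear model with 4 group means was fitted to all 12 libraries, which share one estimate of the spread, with moderated variances (trend and robust options). The contrasts were CR minus WTR, TCR minus TWTR, TWTR minus WTR, TCR minus CR and the interaction, (TCR minus CR) minus (TWTR minus WTR), and p-values were adjusted by Benjamini-Hochberg within each contrast with a threshold of 0.05. Every log2 difference is on the log2(FPKM + 1) scale, which understates the change of low models. The submitters' design text names DESeq2 for the authors' own calls; that tool needs counts and was not used here. A moderated F test over the 4 groups served to class models by their highest and lowest group. Single measures per library were compared by exact two-sided permutation tests, which with 3 libraries against 3 cannot give a p below 0.1.

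The procedure was tested on simulated data for CR minus WTR with 19929 models, 200 of them changed. It recovered 37 of 67 models changed by 1.5-fold (55.2%), 56 of 67 changed by 2-fold (83.6%) and 64 of 66 changed by 4-fold (97.0%), and 7 of the 164 calls were false. In the same simulation 12 of 167 calls were false in TCR minus CR and 11 of 134 in the interaction. The 1 call made in TCR minus TWTR was false, and none was made in TWTR minus WTR. The shares in TCR minus CR and the interaction exceed the nominal 5 in 100. The simulated noise was normal and independent between models, and far fewer models changed than the 40.1% called in CR minus WTR. These rates therefore need not hold for the real libraries. Alternatives covered the pseudocount, the filter on low values, median-of-ratios, quantile and TPM scaling, the replicate number as a term in the model, fits of only the compared groups, moderation without trend or robust options, a required doubling, and leaving out each library in turn. Classes by level and by group profile, and a fit without models at 0 in a single library, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.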

Results

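Root transcriptomes were profiled in 4 groups of 3 libraries, coded WTR, TWTR, CR and TCR in the sample titles, in a series on a tobacco mutant of NtLHT1 grown at low nitrogen. LHT1 proteins are amino acid importers of the plasma membrane. The deposited FPKM table listed 25273 gene models, of which 520 were at 0 in every library and 19929 were tested. CR replicate 2 had 1.81 times the depth of CR replicate 1, and the other 10 libraries lay between 0.914 and 1.14 times that depth. Absolute depth was unknown.

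The 4 groups separated from one another in the principal components of log2(FPKM + 1). CR lay at one end of the first component (37.2% of variance), with scores from -60.3 to -53.4, and TWTR at the other, from 34.8 to 40.1, with TCR next to it at 21.5 to 25.5. WTR stood apart on the second component (20.4%), at -47.8 to -43.5 against 6.7 to 23.2 in the other groups. The third component (9.21%) parted TCR, at 24.5 to 28.8, from TWTR, at -30.6 to -11.2. Libraries of one group correlated at 0.972 to 0.983. Between groups the mean correlation was highest for TWTR with TCR (0.968) and lowest for TWTR with CR (0.926).

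**Figure D1:**
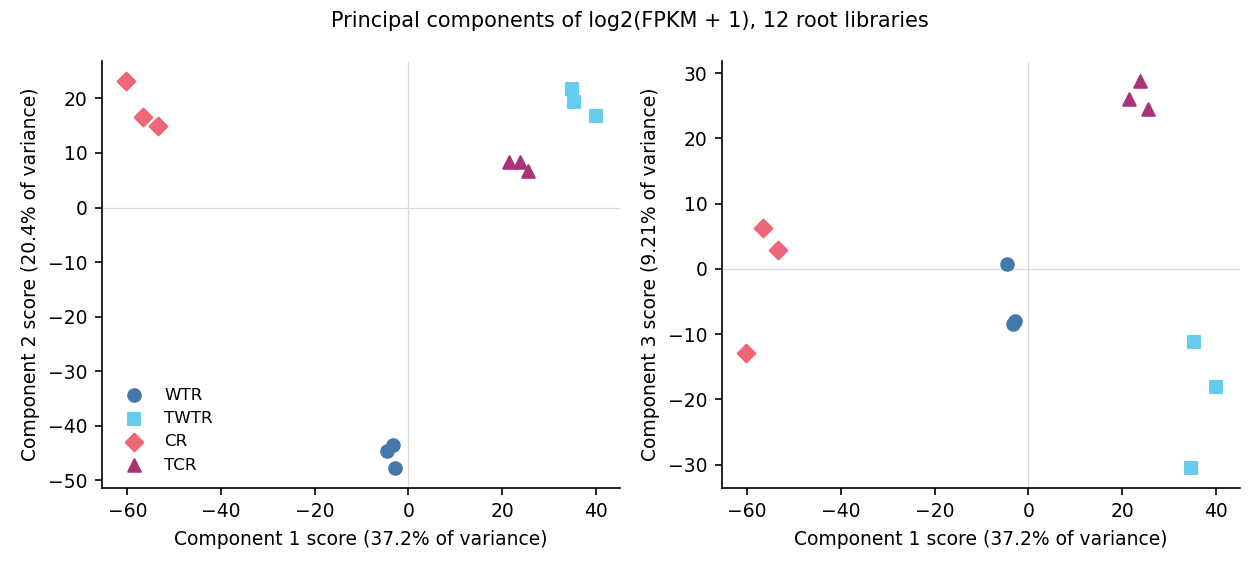
Scores of the 12 root libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2(FPKM + 1), 1 point per library, with the share of variance on each axis. CR and TWTR lie at opposite ends of component 1, WTR is alone at the low end of component 2, and TCR and TWTR part on component 3.

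The libraries also differed in how the signal was spread over gene models. CR roots had 19779 ± 29.9 models at 1 FPKM or more and WTR roots 19444 ± 45.5 (SD, n = 3 each), a difference of 335 models with an exact permutation p of 0.1, the smallest that 3 libraries against 3 can give. TWTR and TCR lay between them, at 19585 ± 48.4 and 19620 ± 35.1. The 10 most abundant models held 4.14% ± 0.226 of the FPKM sum in CR, 5.87% ± 0.46 in WTR, 6.66% ± 0.162 in TWTR and 6.16% ± 0.0233 in TCR (SD, n = 3 each). The model with the highest mean over all libraries, Nitab4.5_0000037g0360, was singled out after its values were seen. It stood at 4829 ± 2005 FPKM in CR against 18795 ± 4338 in WTR, 19557 ± 1453 in TWTR and 16203 ± 491.6 in TCR (SD, n = 3 each). Its CR minus WTR log2 difference was -2.02 (SE 0.256, limma adjusted p 0.000164) and its TCR minus CR difference 1.83 (SE 0.256, limma adjusted p 0.000275).

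CR and WTR roots differed in 7991 gene models, 40.1% of those tested, with 4674 higher and 3317 lower in CR. Most differences were modest, with a median absolute log2 difference of 0.525 among the models called, and 1042 models were at least doubled and 327 at least halved. Among models with a mean of 1 to 5 FPKM, 326 were at least doubled and 65 at least halved; at 100 FPKM and more the counts were 101 and 88. Among models that met the naming rule, the largest rise was in Nitab4.5_0000900g0150. It went from 0.71 ± 0.802 FPKM in WTR to 121 ± 33.2 in CR (SD, n = 3 each, log2 difference 6.24, SE 0.337, limma adjusted p 1.47e-07). Nitab4.5_0000919g0090 rose from 0.853 ± 0.214 to 66.8 ± 3.77 FPKM (log2 difference 5.20, SE 0.183, limma adjusted p 2.87e-09). Both models stood below 6 FPKM on average in TWTR and TCR. Nitab4.5_0001039g0010 fell from 67.1 ± 1.40 to 4.37 ± 0.437 FPKM (log2 difference -3.67, SE 0.0652, limma adjusted p 2.47e-11), and Nitab4.5_0003558g0020 from 58.9 ± 14.1 to 4.27 ± 2.41 (log2 difference -3.57, SE 0.361, limma adjusted p 3.33e-05). The split between higher and lower models depended on scaling. Quantile normalization gave 44.5% of calls higher in CR in place of 58.5%, and 63.6% in place of 76.1% among models changed by a doubling or more. With a pseudocount of 5, the doubled and halved models numbered 503 and 174.

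**Figure D2:**
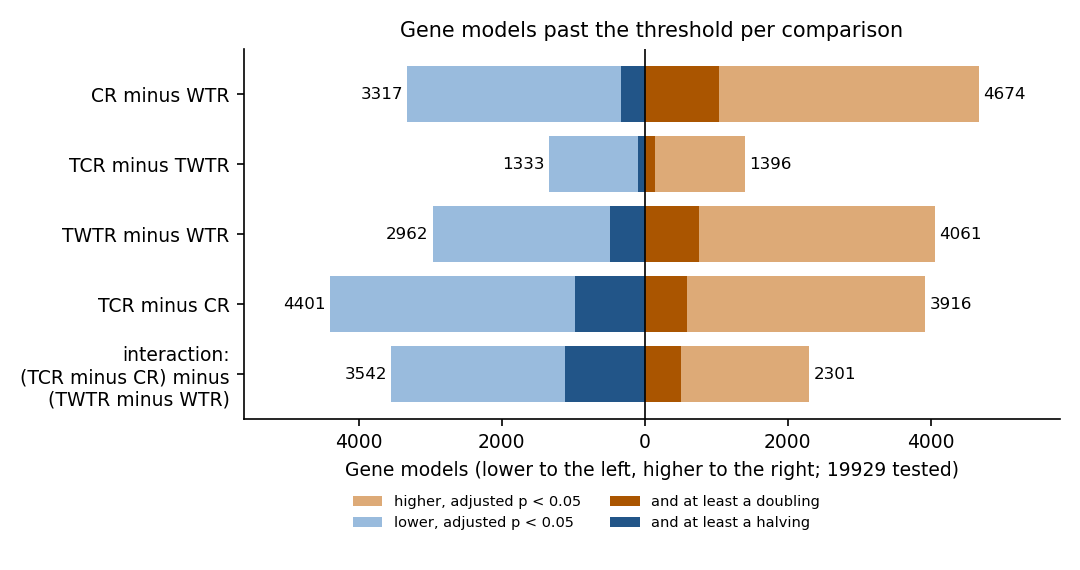
Gene models past an adjusted p of 0.05 in each contrast, higher to the right and lower to the left of 0, out of 19929 tested; the dark part of each bar is the models changed by a doubling or more. TCR minus TWTR has the shortest bars, with 1396 models higher and 1333 lower.

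TCR and TWTR roots differed in 2729 models, 13.7% of those tested, with 1396 higher and 1333 lower in TCR. A doubling or more was seen in 137 of the models that rose and 96 of those that fell, and with a pseudocount of 5 in 34 and 36. Rescaling to TPM turned the split of all calls from 51.2% to 46.7% higher, while median-of-ratios scaling moved it to 57.7%. Nitab4.5_0002076g0130 fell from 36.2 ± 4.21 FPKM in TWTR to 1.55 ± 0.860 in TCR (SD, n = 3 each; log2 difference -3.92, SE 0.340, limma adjusted p 3.43e-05), and it averaged 1.13 in WTR and 2.31 in CR. The other 3 models chosen by the rule were listed at 0 in all libraries of one group, for which no fold is given. Nitab4.5_0002184g0100 was at 0 in TWTR and at 19, 6.8 and 14.77 FPKM in TCR (limma adjusted p 0.0244), and Nitab4.5_0003160g0090 was at 0 in TWTR and at 6.58, 9.64 and 10.44 in TCR (limma adjusted p 0.0261). Nitab4.5_0002050g0010 was at 36.95, 33.6 and 56.24 FPKM in TWTR and at 0 in TCR (limma adjusted p 0.0356). These 3 calls depended on which libraries entered the fit. The call of Nitab4.5_0002184g0100 ended without TCR replicate 1 or 3 or any TWTR library (adjusted p up to 0.0834). The calls of Nitab4.5_0003160g0090 and Nitab4.5_0002050g0010 ended without any one of the 6 libraries compared (up to 0.0783 and 0.0958). With the replicate number as a term in the model, the call of Nitab4.5_0002050g0010 ended too (limma adjusted p 0.0539). In a fit of TCR and TWTR alone the adjusted p-values from limma were 0.0012, 0.000324 and 5.9e-05. In the fit of all 4 groups without WTR replicate 3, limma adjusted p was 4.12e-05 for the first and 6.84e-05 for the last model. Without WTR replicate 2 it was 1e-05 for Nitab4.5_0003160g0090. Each library left out here was the only one of WTR with a value above 0 for that model. Leaving out TCR replicate 1 lowered the counts to 828 higher and 839 lower, leaving out TCR replicate 2 to 840 and 823, and without TWTR replicate 3 the lower count was 865.

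TWTR and WTR roots differed in 7023 models, 35.2% of those tested, with 4061 higher and 2962 lower in TWTR; 755 were at least doubled and 490 at least halved, or 372 and 298 with a pseudocount of 5. The excess of higher calls (57.8%) came close to an even split with median-of-ratios scaling (50.3%) and quantile normalization (50.5%). Nitab4.5_0000109g0460 rose from 0.473 ± 0.333 FPKM in WTR to 31.4 ± 3.55 in TWTR (SD, n = 3 each; log2 difference 4.47, SE 0.189, limma adjusted p 8.04e-09). Nitab4.5_0003363g0020 was listed at 0 in WTR and at 19.83, 31.07 and 11.93 FPKM in TWTR (limma adjusted p 0.00051). Among models that met the naming rule, those with the largest falls carried adjacent identifiers on one scaffold. Nitab4.5_0000712g0280 fell from 190 ± 19.1 to 10.1 ± 2.21 FPKM (log2 difference -4.12, SE 0.141, limma adjusted p 2.27e-09), and Nitab4.5_0000712g0270 from 75.2 ± 5.51 to 3.93 ± 1.11 (log2 difference -3.97, SE 0.191, limma adjusted p 3.5e-08). Both also fell from CR to TCR, with log2 differences of -3.31 (limma adjusted p 8.45e-09) and -3.23 (limma adjusted p 1.48e-07).

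TCR and CR roots differed in 8317 models, 41.7% of those tested, with 3916 higher and 4401 lower in TCR. Here 586 models were at least doubled and 981 at least halved, or 341 and 580 with a pseudocount of 5. The direction of the split turned under quantile normalization, with 53.7% of calls higher in place of 47.1%. Nitab4.5_0000790g0050 rose from 0.287 ± 0.0503 FPKM in CR to 16.9 ± 2.88 in TCR (SD, n = 3 each; log2 difference 3.79, SE 0.188, limma adjusted p 2.18e-08), and it also rose from 1.45 in WTR to 14.6 in TWTR (limma adjusted p 5.36e-07). Nitab4.5_0002050g0010 was at 78.27, 54.46 and 19.6 FPKM in CR and listed at 0 in TCR (limma adjusted p 0.0118). The remaining pair rested on values that included zeros. Nitab4.5_0001639g0070 was at 7.7, 0 and 7.6 FPKM in CR and at 48.84, 70.56 and 76.57 in TCR (limma adjusted p 0.04), and the call ended without any one of the libraries of CR, TCR or WTR (adjusted p up to 0.122 without CR replicate 2) and with a pseudocount of 0.1 (0.119). Nitab4.5_0000302g0080 was at 224.12, 210.28 and 274.21 FPKM in CR and at 0, 69.43 and 0 in TCR (limma adjusted p 0.0335). That call ended without any CR library or without TCR replicate 1 or 3 (adjusted p up to 0.109), with a pseudocount of 0.1 (0.059), and in a fit of these groups alone (0.0655).

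**Figure D3:**
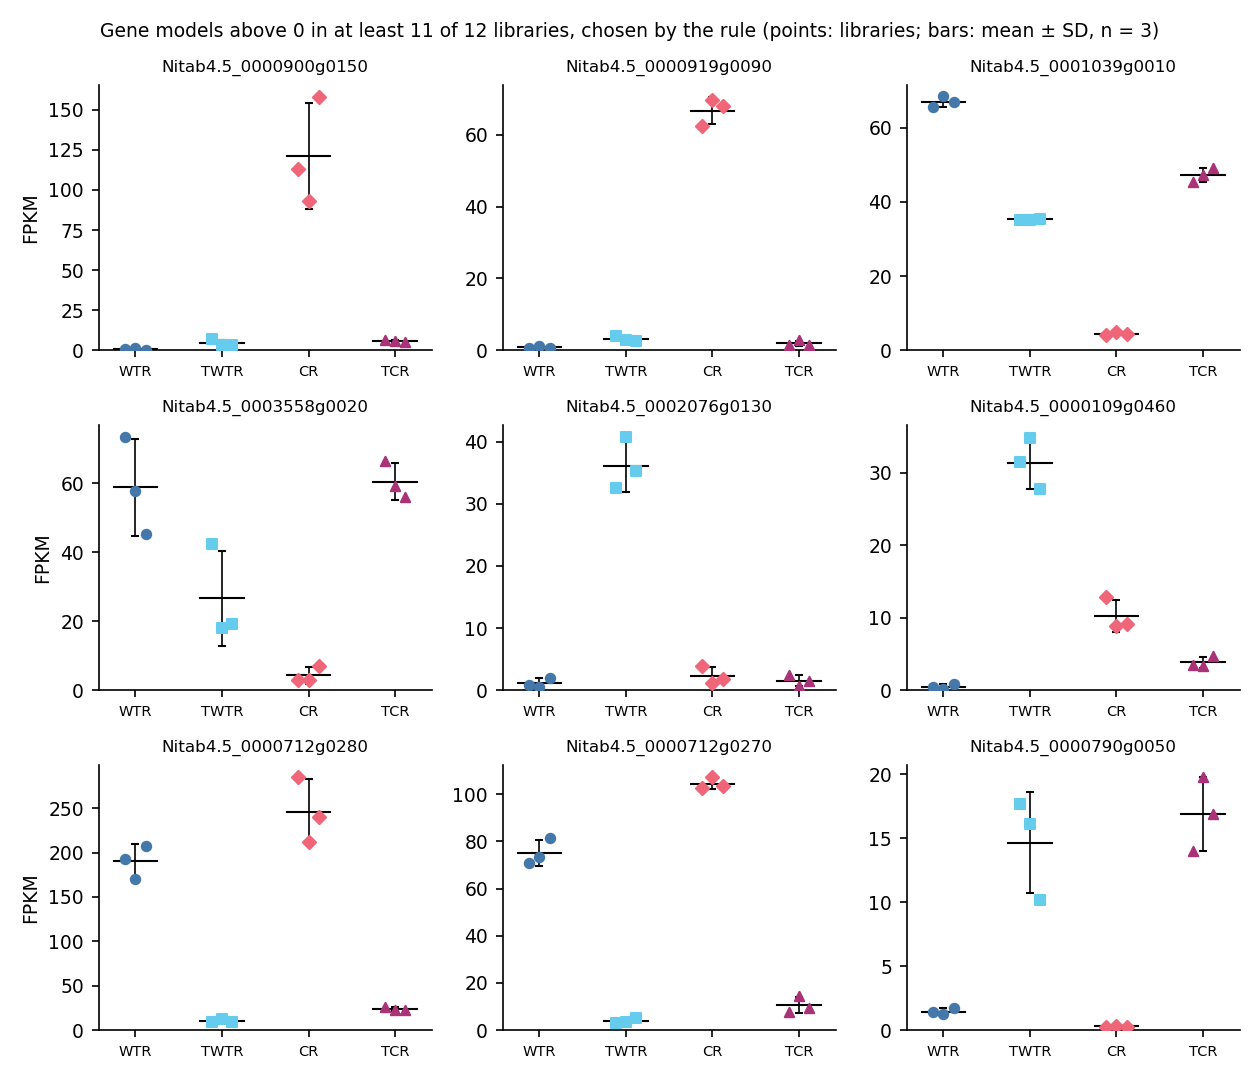
FPKM per library (points), with mean and SD (bars, n = 3), of the 9 gene models named by the rule that were above 0 in at least 11 libraries; each panel has its own axis starting at 0. Nitab4.5_0000900g0150 and Nitab4.5_0000919g0090 stand high in CR, and Nitab4.5_0000712g0280 and Nitab4.5_0000712g0270 are low in TWTR and TCR.

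The difference between CR and TCR was itself tested against the difference between WTR and TWTR. This interaction passed in 5843 models, 29.3% of those tested, with 2301 higher and 3542 lower, and 503 and 1119 of them by a doubling or more (301 and 583 with a pseudocount of 5). All 4 models named by the rule were listed at 0 in some libraries, and the size of their interaction depended on the pseudocount. Nitab4.5_0002050g0010, at 0 in TCR and at 0, 0 and 60.81 FPKM in WTR, had a lower value (limma adjusted p 0.00898). Nitab4.5_0001639g0070, at 0 in CR replicate 2 and TWTR replicate 1, had a higher one (limma adjusted p 0.0335), as had Nitab4.5_0002517g0020 (0.0455), and Nitab4.5_0001418g0040 a lower one (0.0356). Nitab4.5_0002517g0020 was at 11.95, 0 and 9.37 FPKM in WTR, at 12.26, 0 and 18.82 in TCR, and at 0 in TWTR and CR. Nitab4.5_0001418g0040 was at 52.47, 24.2 and 17.51 FPKM in CR, at 0 in TCR, at 16.62, 15.07 and 0 in TWTR and at 17.61, 0 and 0 in WTR. The call of Nitab4.5_0001639g0070 ended without CR replicate 2, any TCR library or WTR replicate 2 or 3 (adjusted p up to 0.0754) and with a pseudocount of 0.1 (0.0909). That of Nitab4.5_0002517g0020 ended without any CR or TWTR library, TCR replicate 1 or 3, or WTR replicate 1 or 3 (up to 0.0977), with a pseudocount of 5 (0.0532) and after rescaling to TPM (0.0502). For Nitab4.5_0001418g0040 it ended without any CR or TCR library, TWTR replicate 1 or 2, or WTR replicate 2 or 3 (up to 0.0821). Quantile normalization gave 52.1% of interaction calls higher in place of 39.4%, and 42% in place of 31% among those of a doubling or more.

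Log2 differences were compared over genes between contrasts made from disjoint libraries. CR minus WTR and TCR minus TWTR had a Pearson r of 0.0328 and a Spearman rho of 0.0386 over 19929 genes, which are not independent replicates, and r was smaller than its jackknife error over libraries (0.0531). The calls of these contrasts overlapped in both directions: 565 models were higher in both (327 if the lists were independent) and 288 lower in both (222). Another 500 were higher in the first and lower in the second (313) and 363 the reverse (232). The share of models called rose with mean level. From 1 to 5 FPKM to 100 FPKM and more, it rose from 28% to 53.6% in CR minus WTR and from 5.94% to 27.2% in TCR minus TWTR. Independent lists do not allow for level, here or in the next pair of contrasts. Nor do they allow for the spread, which was estimated once per model from all 12 libraries. A model with a small spread passes more readily in both contrasts, whatever the directions. An excess in every direction therefore need not mean that the contrasts share changes. Overlap among models of like level and spread was not tested. Without TCR replicate 1 these overlaps came to 556 models in the same and 570 in the opposite direction, and without TCR replicate 2 to 546 and 570. TWTR minus WTR and TCR minus CR were related more closely, with r 0.323 (jackknife error 0.0364) and rho 0.289. They shared 1634 models higher in both (798 if independent) and 1533 lower in both (654), and 655 and 400 models went opposite ways (897 and 582 if independent).

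**Figure D4:**
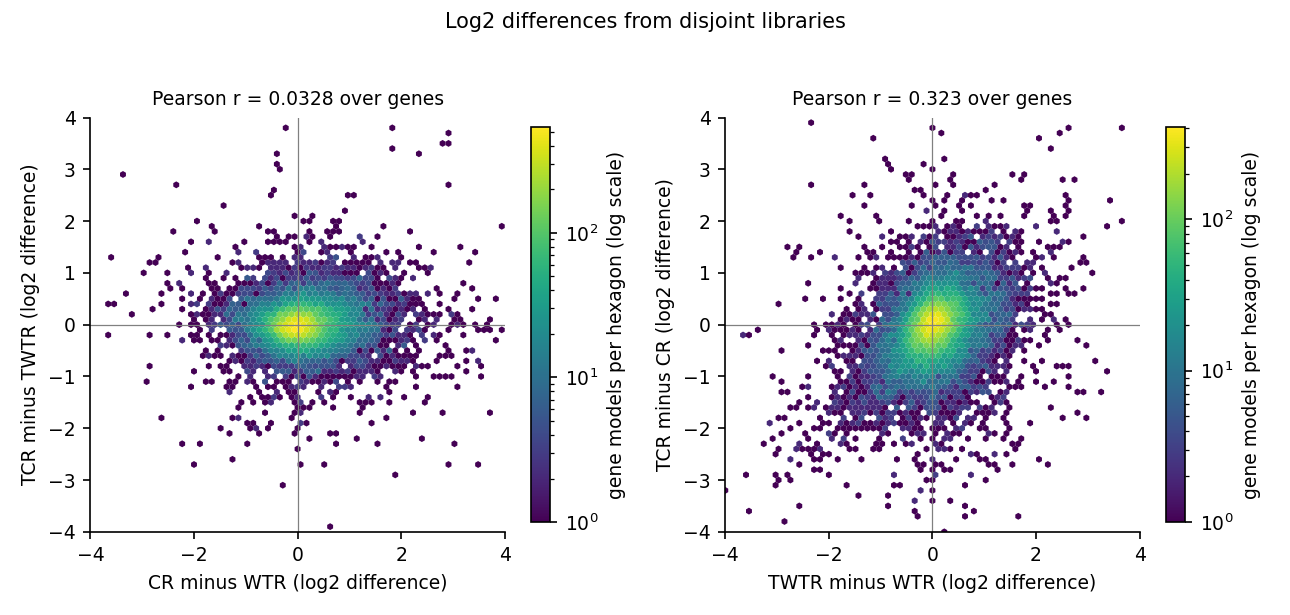
Log2 differences per gene model for CR minus WTR against TCR minus TWTR (left) and TWTR minus WTR against TCR minus CR (right), as counts of models per hexagon on a log colour scale. The left cloud shows little slope (r 0.0328) and the right one a positive slope (r 0.323); 15 and 13 models beyond 4 on either axis are not drawn.

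A moderated F test over the 4 groups passed in 11811 models. CR had the highest mean in 4528 of them (38.3%), TWTR in 3451 (29.2%), WTR in 2191 (18.6%) and TCR in 1641 (13.9%). CR also had the lowest mean most often, in 3801 (32.2%), against 3433 (29.1%) for WTR, 2945 (24.9%) for TWTR and 1632 (13.8%) for TCR. In 12 models groups tied for the lowest mean, and the first in the order WTR, TWTR, CR and TCR was counted. These shares were not computed under other scalings. CR was above every library of all other groups, with means at least doubled, in 408 models and below them in 144; the counts were 47 and 33 for TWTR, 22 and 123 for WTR, and 19 and 2 for TCR. With a pseudocount of 5 the counts were 211 and 81 for CR, 17 and 8 for TWTR, 9 and 40 for WTR, and 5 and 0 for TCR. A pseudocount of 0.1 gave 215 models below all others in WTR, 61 in TWTR and 10 in TCR, a mean of at least 5 FPKM left 12 models above all others in TCR, and quantile normalization gave 35 above and 80 below in WTR. Without TWTR replicate 1, 50 models lay below all others in TWTR, and on leaving out libraries the count of 2 in TCR ranged from 1 (without WTR replicate 2) to 9 (without TCR replicate 3) and was 7 without TCR replicate 2 and 4 without TWTR replicate 1, TWTR replicate 2 or WTR replicate 1.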

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

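Tests of neighbours with calls shuffled among models of like level 2 and 5 models apart were chosen only after the results were seen. So was the ratio of counts without libraries other than CR replicate 2. The other tests in this part were fixed before, but a limit on the test 10 models apart was added afterwards. The difference between CR and TCR differed from that between WTR and TWTR, by the interaction test, in 2301 models with a higher and 3542 with a lower value. Assigning the 12 libraries to 4 groups in 100 ways, the real one included, gave 1 assignment with as many models: the real one, at 5843. The highest of the others gave 2272, from an assignment that kept 1 group whole. Mixing libraries of different groups moves the group differences into the spread within groups, so few calls were bound to follow. The low counts therefore do not test the interaction by itself, and only their gap to the real count shows that the groups differ. For the contrasts of 2 groups only 10 splits exist, too few for a share under 0.05. In each, 1 split reached the real count. Low counts in the mixed splits were bound to follow here too. The real counts and the highest of the other splits were 7991 and 1 for CR minus WTR, 2729 and 1 for TCR minus TWTR, 7023 and 2 for TWTR minus WTR, and 8317 and 1 for TCR minus CR.

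The interaction passed in 12 of the 17 named models, with limma adjusted p from 3.37e-10 to 0.0455, and in 29.3% of all models tested. The count among named models is partly built in. The rule named some of them for a passing interaction and the others for large differences that enter into it. On the log2 scale it was -5.905 for Nitab4.5_0000900g0150, -5.757 for Nitab4.5_0000919g0090, 4.077 for Nitab4.5_0001039g0010 and 4.831 for Nitab4.5_0003558g0020, which are the models named for CR minus WTR. It was -4.523 for Nitab4.5_0002076g0130, -5.691 for Nitab4.5_0000109g0460, 0.8155 for Nitab4.5_0000712g0280 and 1.14 for Nitab4.5_0000790g0050. It was 6.308 for Nitab4.5_0001639g0070, which was at 0 in CR replicate 2 and TWTR replicate 1. Models listed at 0 in a whole group gave -8.905 (Nitab4.5_0002050g0010), 5.036 (Nitab4.5_0002517g0020) and -6.178 (Nitab4.5_0001418g0040), sizes that depend on the pseudocount. With pseudocounts of 0.1 and 5 the values were -14.38 and -5.281, 9.33 and 2.441, and -10.53 and -3.393, in that order, and 8.609 and 4.478 for Nitab4.5_0001639g0070. For Nitab4.5_0002050g0010 the value was -10.89 without WTR replicate 3. It did not pass in Nitab4.5_0000712g0270 (0.744, adjusted p 0.06), Nitab4.5_0003363g0020 (adjusted p 0.071), Nitab4.5_0002184g0100 (0.302), Nitab4.5_0003160g0090 (0.578) or Nitab4.5_0000302g0080 (0.716).

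More models differed in CR minus WTR than in TCR minus TWTR, by a ratio of 2.93. Leaving out 1 library gave ratios from 2.41 (CR replicate 1) to 4.65 (TCR replicate 1), with 4.64 without TCR replicate 2. Without the more deeply sequenced CR replicate 2 the ratio was 2.84, and with median-of-ratios scaling it was 2.93, which argues against depth of that library and against a shift of scale by a few abundant genes. With replicate variance taken out, log2 differences had a standard deviation over genes 1.96 times as large in CR minus WTR. The lowest of 10000 bootstrap draws of genes was 1.77, and such draws do not measure the spread between libraries. The differences themselves were thus larger in CR minus WTR in these libraries. One spread per model served all groups, so both contrasts had the same SE (median 0.1144). A larger replicate spread in TCR and TWTR would have weighed on both alike, so its hiding of equal differences was not put to a test. No biological explanation was tested, since the labels do not say what the codes stand for, and a batch that goes with the codes stays open.

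Neighbours were taken among the tested models of a scaffold in the order of their identifiers. Untested models between them were skipped, so neighbours need not lie directly side by side. In CR minus WTR 1668 neighbouring pairs were called in the same direction, more than under shuffled calls (mean 1397, highest 1511 in 1000 permutations). The counts of TWTR minus WTR (1226, highest 1159) and TCR minus CR (1739, highest 1588) also lay above theirs. TCR minus TWTR, with fewer such pairs, had a like ratio (1.18 against 1.19) but lay inside its permutations (187, highest 196). In CR minus WTR, differences in mean level are argued against by a ratio of 1.19 with calls shuffled among models of like level, and short scaffolds of another origin by a ratio of 1.24 on scaffolds of 20 or more models, both above every permutation. On those scaffolds TWTR minus WTR (284 pairs, highest 306) and TCR minus TWTR (36 pairs, mean 40.77) lay inside the permutations, so this argument does not extend to them. Split gene models or reads shared between neighbours stay open. In CR minus WTR the count of 401 pairs 10 models apart lay inside the permutations (ratio 1.12, highest 419), unlike that 1 apart. This was the outcome set beforehand for such a cause. The limit added afterwards is that an excess of the size seen 5 apart (1.12) would not have stood out 10 apart. The highest permutation there was 1.17 times the mean. Against pairs of direct neighbours as the whole cause stand 1359 pairs 2 models apart in CR minus WTR (highest among models of like level 1282). TCR minus CR also lay above its permutations (1388, highest 1350). The argument does not extend to TWTR minus WTR (997, highest 1004), TCR minus TWTR (143, highest 174) or the interaction (742, highest 745). In CR minus WTR the outcome 5 apart turned on the shuffle. Its 820 pairs lay above every free permutation (highest 809) and inside those among models of like level (ratio 1.1, highest 822). Longer runs of split or copied models therefore cannot be told apart from neighbours regulated together.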

How the results depend on the processing

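Not every value was free to move. The replicate term and the moderation options leave agreements as they were. Leaving out a library of another group leaves the log2 differences of a contrast of 2 groups as they were. The jackknife error came from the same fits without 1 library that it judged. With these limits, 264 counts of calls and agreements between contrasts stayed under the alternatives and 18 moved. To stay, counts had to lie within 1.5 times and agreements within the jackknife error. Quantile normalization nevertheless turned which side had more calls, to 3656 higher and 4552 lower in CR minus WTR, 4566 and 3929 in TCR minus CR, and 3042 and 2794 in the interaction, and rescaling to TPM to 1277 and 1459 in TCR minus TWTR; the cause was not tested. Requiring a doubling left 1042 higher and 327 lower in CR minus WTR, 137 and 96 in TCR minus TWTR, 755 and 490 in TWTR minus WTR, 586 and 981 in TCR minus CR, and 503 and 1119 in the interaction, from 4674, 3317, 1396, 1333, 4061, 2962, 3916, 4401, 2301 and 3542; a stricter criterion removes calls by construction. Leaving out 1 library moved TCR minus TWTR between 828 and 1491 higher and between 823 and 1405 lower; the cause was not tested. The agreement of TWTR minus WTR with TCR minus CR moved from 0.323 to 0.2543 with pseudocount 0.1, 0.3743 with pseudocount 5 and 0.3662 with a mean of at least 5 FPKM; the cause was not tested. With the replicate number as a term (replicate block), calls were 4441 and 3145, 1194 and 1131, 3860 and 2798, 3757 and 4251, and 2148 and 3339, in the same order. The 18 same-number pairs of libraries had correlations of deviations from -0.0888 to 0.0991, and the 36 different-number pairs from -0.183 to 0.216. No strong signal went with the replicate numbers, but weak correlations cannot show that the libraries were not paired. The block ended the call of Nitab4.5_0002050g0010 in TCR minus TWTR (adjusted p 0.0539; 5.9e-05 to 0.0958 over its alternatives) and of no other named model. For named models 387 values kept their call, 64 lost it and none reversed. The fit without models at 0 in a single library, chosen after seeing the data, gave 4687 and 3329 calls in CR minus WTR. The gene list alternatives and the fit of reference-named models alone were not run, as no identifier had a name. Depth is known only relative to CR replicate 1, so low models carry counting error of unknown size.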

Other observations

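The test below was chosen only after the models at 0 were seen. In 129 models, 1 library was listed at 0 while both others of its group were at 5 FPKM or more, of which 127 were tested, 14 were called in a contrast and 3 were among those named. A candidate explanation is that few fragments lie behind the values of these models in every library. In the 84 tested models where this happened in a single group, the median replicate standard deviation in the other 3 groups was 0.756 on the log2 scale, against 0.183 in models of like level, a ratio of 4.14 (95% bootstrap interval 3.67 to 5.88). A wide spread in groups not used to choose the models argues against a failure confined to single libraries. Few fragments would also widen the spread, but the size of that effect was not computed. Reads split unevenly between near-identical gene copies could do the same and cannot be told apart from few fragments here. FPKM alone may thus overstate how well such models were measured, and no biological explanation was tested.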
